A study of Rattus norvegicus with 4 samples.

How the data were processed

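Primordial germ cells were collected from F3 embryos at day 13 of gestation and enriched by sedimentation at unit gravity to more than 85% purity, per the labels' protocols. DNA of several animals was combined into 2 pools per lineage, sonicated with a 300 bp program, denatured and immunoprecipitated with a monoclonal antibody against 5-methylcytidine, and the recovered DNA was sequenced, per the labels' protocols. MeDIP-seq measures how many sequenced fragments carry methylated cytosines, so its signal depends on CpG density, on the number of DNA copies and on the efficiency of each precipitation, and it gives no methylation percentage. The design text of the series gives a different number of pools and a different stage in places. The samples' own labels were followed.

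The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR and the genome build Rnor_6.0. Their versions, the counting step, read extension and the handling of duplicates are not given in the sources used here. The deposited table holds, per the file headers, raw read counts per 100 bp window in each pool. The counts are whole numbers, no window exceeds 300 in any pool, and 5 to 30 windows per pool stand at 300, so the authors' counts look limited there. The deposited RPKM values are the authors' counts divided by window length and reads per pool. They were used only to obtain the number of reads behind each pool, which was lower than the sum of its window counts. Each read was counted in 1.5 windows on average, so neighbouring windows share reads and are not independent. The table also holds the authors' mean count and mean RPKM per lineage, which were not used. The deposited log2 fold changes and log2 CPM are the authors' edgeR values, with the control lineage over the vinclozolin lineage, so the sign was turned here. The deposited p-values and adjusted p-values are the authors' and are given for the 2318150 windows with at least 40 reads over the 4 pools. That is the same set as the filter of a mean count of 10 fixed for the tests here. Every per-sample column matched the labels of 1 sample.

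Lineage came from the samples' labels. The main test was edgeR 4.0.16 in R 4.3.3 (glmQLFit with legacy = FALSE and robust = TRUE, then glmQLFTest) on the deposited counts of windows with a mean count of at least 10, with the total window count as library size, TMM factors (0.936, 1.08, 0.908 and 1.10 for control pools 1 and 2 and vinclozolin pools 1 and 2), lineage as the only term and Benjamini-Hochberg adjustment over all tested windows. Fold changes are vinclozolin over control. Windows at an unadjusted p under 1e-04 that changed the same way and lay within 1000 bp of each other were merged into regions. Named regions are the 12 higher and 12 lower with the smallest p of their best window among those in which both vinclozolin pools lay on the same side of both control pools. CPM values of windows use TMM-scaled totals and those of 10 kb runs use plain totals. Shares and X or Y ratios were compared with two-sided exact permutation tests, which cannot go below p = 0.33 with 2 pools per lineage. The filter, tests, thresholds, naming rule and the alternatives listed as planned were fixed before the data were examined.

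Tiles of 10000 bp and their runs were added after seeing the data. They used the same test, a mean count of at least 10, tiles at an unadjusted p under 0.001 within 10000 bp of each other and at least 2 such tiles per run. Low-count windows inside runs, those with a mean count from 1 to under 5 at least 300 bp from any window with a mean count of 5 or more, were compared per pool with such windows genome-wide.

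The test was tested on simulated data with the real means, library sizes and a common dispersion of 0.0278. Among 2318150 windows it called 0 of 67 windows changed 2-fold (0%), 28 of 67 changed 4-fold (41.8%) and 46 of 66 changed 8-fold (69.7%), with 1 false call, and 5.00% of unchanged windows had p under 0.05. Among 274930 tiles of 10 kb it called 5 of 100 changed 1.5-fold (5%) and 56 of 100 changed 2-fold (56%), with 4 false calls and a dispersion of 0.0177. The simulated pools differed by lineage and chance only. In the real fits 2.67% of windows and 2231 of the 274930 tiles had p under 0.05. Among unchanged simulated tiles the share was 4.96%. The real fits, with lineage as the only term, were thus more conservative than the simulated ones. The shares called may overstate what could be recovered in these data. With the pool number as a replicate block, 4.2% of windows and 11688 of the 274930 tiles had p under 0.05 in edgeR, nearer the simulated shares. The main fit leaves differences by pool number in its spread. A 2-fold change of a window was not detectable at this depth with 2 pools per lineage.

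Alternatives covered scaling by total counts or DESeq2 size factors, each pool left out in turn, a replicate block, the edgeR exact test, the DESeq2 1.42.0 Wald test (run in 10 interleaved parts with common size factors), filters at a mean count of 5 and 20 and at 1 read, 1 window in every 5, tiles of 1000 bp, other thresholds and merge distances. A correction for each pool's trend with mean count, an earlier edgeR quasi-likelihood method and tiles of 100 kb and 1 Mb were added later. Tables were handled with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15. A genome sequence and a gene annotation of Rnor_6.0 were not used here, so the planned tests of promoters and gene lists, the correction for CpG density and the comparison of genomic features by CpG number were not run, and regions carry positions without gene names.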

Results

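DNA methylation was profiled by methylated DNA immunoprecipitation and sequencing (MeDIP-seq) in primordial germ cells, the embryonic precursors of sperm and eggs, of male rat embryos at day 13 of gestation. The embryos belonged to the F3 generation of 2 lineages of outbred Sprague Dawley rats. In the vinclozolin lineage, the F0 females had been injected with vinclozolin, an agricultural fungicide whose metabolites block the androgen receptor, at 100 mg per kg body weight on each of days 8 to 14 of gestation. The F0 females of the control lineage received the DMSO vehicle. Each lineage was represented by 2 pools of germ cells from different animals, so the spread between pools includes biological differences. Reads were counted by the authors in 27820300 windows of 100 bp over the rat genome (build Rnor_6.0). The window counts summed to 121286596 in control pool 1, 102811677 in control pool 2, 72569603 in vinclozolin pool 1 and 110884221 in vinclozolin pool 2. At least 1 read was present in 74.4% of the windows in control pool 1, 62.6% in control pool 2, 64.7% in vinclozolin pool 1 and 62.2% in vinclozolin pool 2.

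The first comparison asked where methylation signal in germ cells of the F3 generation, which was never exposed directly, differed between the lineages. The candidate regions with the smallest p were short, and in the main fit more of them had lower than higher signal in the vinclozolin lineage, a majority that shrank or turned under some alternatives. The 2318150 windows with at least 10 reads on average were tested. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 windows passed an adjusted p of 0.05, and the lowest adjusted p was 0.903. At an unadjusted p under 0.05 there were 61959 windows (2.67%), and at p under 1e-04 there were 58, of which 16 were higher and 42 lower in the vinclozolin lineage. Chance alone would give 232 windows at p under 1e-04. With the pool number as a replicate block, which no label marks as a batch, there were 118 higher and 147 lower windows at that threshold. Scaling by total counts alone gave 8 higher and 13 lower windows, which moved the higher share from 27.6% to 38.1%. The DESeq2 Wald test gave 0 windows at an adjusted p of 0.05 and 2537 at an unadjusted p under 0.05. In the authors' deposited table, 22 windows were higher and 56 lower at p under 1e-04, 0 passed an adjusted p of 0.05, and 47 of the 58 windows found here were among them. The counts depended on single pools. Without 1 pool, a lineage keeps 1 pool, its own spread is not measured, and lineage is partly mixed with pool number. Splitting the 4 pools by number gave 3425 windows past an adjusted p of 0.05 in edgeR. Of these, 2924 were lower in the pools numbered 2. Windows past an adjusted p of 0.05 numbered 0 without control pool 1, 6 without control pool 2, 228 without vinclozolin pool 1 (12 higher, 216 lower) and 1215 without vinclozolin pool 2 (1164 higher, 51 lower).

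Merging windows at p under 1e-04 that lay within 1000 bp of each other gave 14 regions of higher and 33 of lower signal in the vinclozolin lineage. With the trend of each pool with mean count removed, an alternative added after seeing the data, there were 34 higher and 39 lower regions. Without vinclozolin pool 2 most regions were higher, in a fit that partly mixes lineage with pool number. In all 47 the vinclozolin pools lay on the same side of both control pools, an arrangement that chance gives at 33.3% of windows and that selection by p favours. Only 1 higher and 7 lower regions held 2 or more windows. The 12 higher and 12 lower regions with the smallest p are described next, by position only, because genes were not analysed here. None of the 24 reached an adjusted p of 0.05 in the main fit, which had lineage as its only term.

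The higher region with the smallest p lay on chromosome 13 from 71473201 to 71473500. Its best window held 0 reads in control pool 1, 12 in control pool 2, 30 in vinclozolin pool 1 and 42 in vinclozolin pool 2, or 0.054 ± 0.077 CPM in the control and 0.401 ± 0.077 CPM in the vinclozolin lineage (SD, n = 2 each), where CPM are counts scaled to library size. The log2 fold change was 2.83 ± 0.49 (SE) with an adjusted p of 0.903 in edgeR. Without control pool 1, which had no read there, it was 1.84. Without control pool 2, where the remaining control pool had no read, it was 8.30. It was 2.66 without vinclozolin pool 1 and 3.04 without vinclozolin pool 2. The most strongly covered higher region was chromosome 8 from 82177301 to 82177400, with 0.585 ± 0.068 CPM in the control and 1.28 ± 0.03 CPM in the vinclozolin lineage (SD, n = 2 each), 2.19-fold higher. A window on chromosome 13 from 53427801 to 53427900 held 4 and 2 reads in the control pools and 13 and 25 in the vinclozolin pools, 7.29-fold higher. The region on chromosome 14 from 12307101 to 12307200 held 22 and 46 against 44 and 90 reads, 2.33-fold higher. On chromosome 7 from 73275901 to 73276000 the 9.32-fold difference rested on vinclozolin pool 2, which held 76 reads against 8 in vinclozolin pool 1 and 4 and 6 in the control pools.

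The other 7 higher regions were single windows on chromosome 18 from 48229501, chromosome 3 from 155025201, chromosome 1 from 133365301 and from 145971501, chromosome 8 from 63620801 and from 46958801, and chromosome 2 from 121755301. Their folds ranged from 2.65 to 6.65. The higher regions were local. Over the 10 kb around each of the 12, the log2 ratio of the vinclozolin to the control lineage lay between 0.06 and 0.49.

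**Figure D1:**
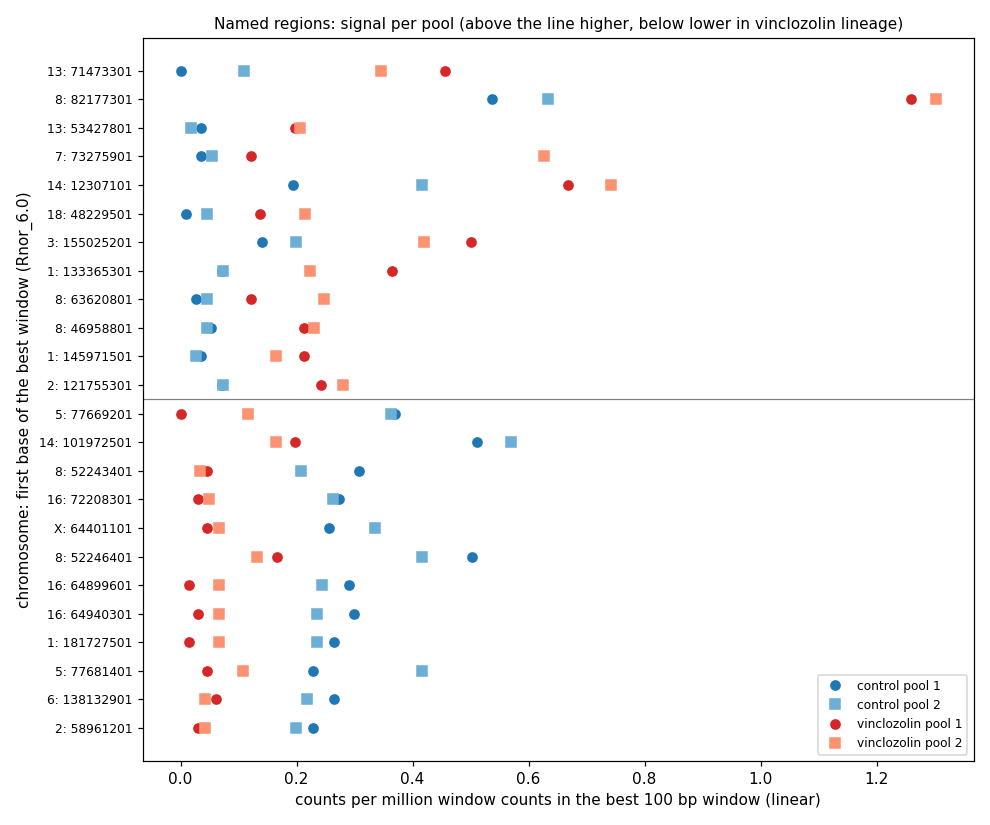
CPM (TMM-scaled, linear axis) in the best 100 bp window of each of the 24 named regions, 1 point per pool; control pools are blue, vinclozolin pools red, circles pool 1 and squares pool 2. The vinclozolin points lie to the right of both control points in the 12 regions above the line and to the left in the 12 below it.

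Among the lower regions, chromosome 5 from 77669101 to 77669300 had the smallest p. Its best window held 42 and 40 reads in the control pools and 0 and 14 in the vinclozolin pools, or 0.366 ± 0.006 against 0.058 ± 0.082 CPM (SD, n = 2 each). The log2 fold change was −2.30 ± 0.44 (SE, adjusted p 0.903 in edgeR). It was −1.66 without vinclozolin pool 1 and −8.15 without vinclozolin pool 2, where the remaining vinclozolin pool had no read. On chromosome 14 from 101972501 to 101972800 the reads were 58 and 63 against 13 and 20, a 3.04-fold lower signal. On chromosome 8 from 52243401 to 52244600 they were 35 and 23 against 3 and 4, 6.72-fold lower, and a neighbouring region from 52246101 to 52246500 was 3.16-fold lower. On chromosome 16 from 72208201 to 72208600 they were 31 and 29 against 2 and 6, 6.14-fold lower. On the X chromosome from 64401101 to 64401200 they were 29 and 37 against 3 and 8, 4.95-fold lower. The remaining 6 were on chromosome 16 from 64899601 and from 64940201, chromosome 1 from 181727501, chromosome 5 from 77681401, chromosome 6 from 138132901 and chromosome 2 from 58961201, with folds of 3.76 to 5.59. Of the 12 lower regions, 6 lay inside longer stretches of lower signal, which are described next.

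Counts summed in tiles of 10000 bp, a scale chosen after seeing the data, showed stretches in which the vinclozolin lineage had about 50% of the control signal. In edgeR's quasi-likelihood test of 274930 tiles, 1 tile passed an adjusted p of 0.05. It lay on chromosome 7 from 10260001 to 10270000. Its window counts summed to 567 and 373 in the control pools and 102 and 159 in the vinclozolin pools. Its log2 fold change was −1.54 ± 0.19 (SE, adjusted p 0.00973), lower in both vinclozolin pools than in either control pool. Without 1 pool at a time the log2 fold change of this tile lay between −1.69 and −1.36. In such fits a lineage keeps 1 pool and its own spread is not measured. The tile missed the adjusted threshold without control pool 1. Under another scaling or the trend correction its adjusted p in edgeR lay between 0.00862 and 0.0276. Without 1 pool at a time the number of tiles past the threshold was 7 (control pool 1), 3 (control pool 2), 19 (vinclozolin pool 1) and 41 (vinclozolin pool 2).

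Of the 274930 tiles, 23 were lower and 1 higher at an unadjusted p under 0.001 in edgeR, a smaller share than the 0.001 that chance would give. They formed 5 runs of at least 2 neighbouring tiles, and all 5 were lower in the vinclozolin lineage. This direction depended on single pools. Higher runs outnumbered lower runs without control pool 1 and without vinclozolin pool 2, but not without either other pool. Such fits partly mix lineage with pool number. In this fit, with lineage as the only term and no replicate block, only the run on chromosome 7 held a tile past the adjusted threshold. That run spanned 10260001 to 10280000, with 11.3 ± 0.6 CPM in the control and 5.64 ± 0.86 CPM in the vinclozolin lineage (SD, n = 2 each). The longest run covered 90 kb of chromosome 16 from 64890001 to 64980000, with 70.5 ± 2.8 against 39.4 ± 3.3 CPM, 0.560 of the control level. Its best tile reached an adjusted p of 0.082 in edgeR. On chromosome 5 from 77660001 to 77690000 the signal was 26.5 ± 2.7 against 12.2 ± 4.6 CPM, with summed window counts of 648 in vinclozolin pool 1 and 1717 in vinclozolin pool 2. The run on chromosome 14 from 101970001 to 102000000 had 25.0 ± 2.3 against 13.6 ± 3.4 CPM, and the run on chromosome 1 from 181720001 to 181740000 had 8.87 ± 1.28 against 4.75 ± 1.03 CPM. The 50 kb on each side of the runs on chromosomes 7 and 16 differed little between lineages, with log2 ratios of 0.01 and −0.01, while those on chromosomes 5, 14 and 1 were −0.23, 0.17 and −0.37. Windows with a mean count from 1 to under 5, at least 300 bp from any window with a mean count of 5 or more, were lower too in both vinclozolin pools than in both control pools in the runs on chromosomes 7, 16, 5 and 1, with log2 differences of −1.09, −1.09, −1.48 and −1.22 relative to such windows genome-wide. On chromosome 14 such windows held 4 reads in all, too few to compare. A single tile on the X chromosome from 150610001 to 150620000 had summed window counts of 805 and 756 against 142 and 388. Its log2 fold change was −1.30 ± 0.19 (SE) with an adjusted p of 0.066 in edgeR. Without 1 pool at a time its log2 fold change lay between −1.86 and −0.97. In such fits a lineage keeps 1 pool and its own spread is not measured. The adjusted p of this tile in edgeR was 0.0276 with total counts as the scale, 0.0847 with DESeq2 size factors and 0.479 with the trend correction.

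**Figure D2:**
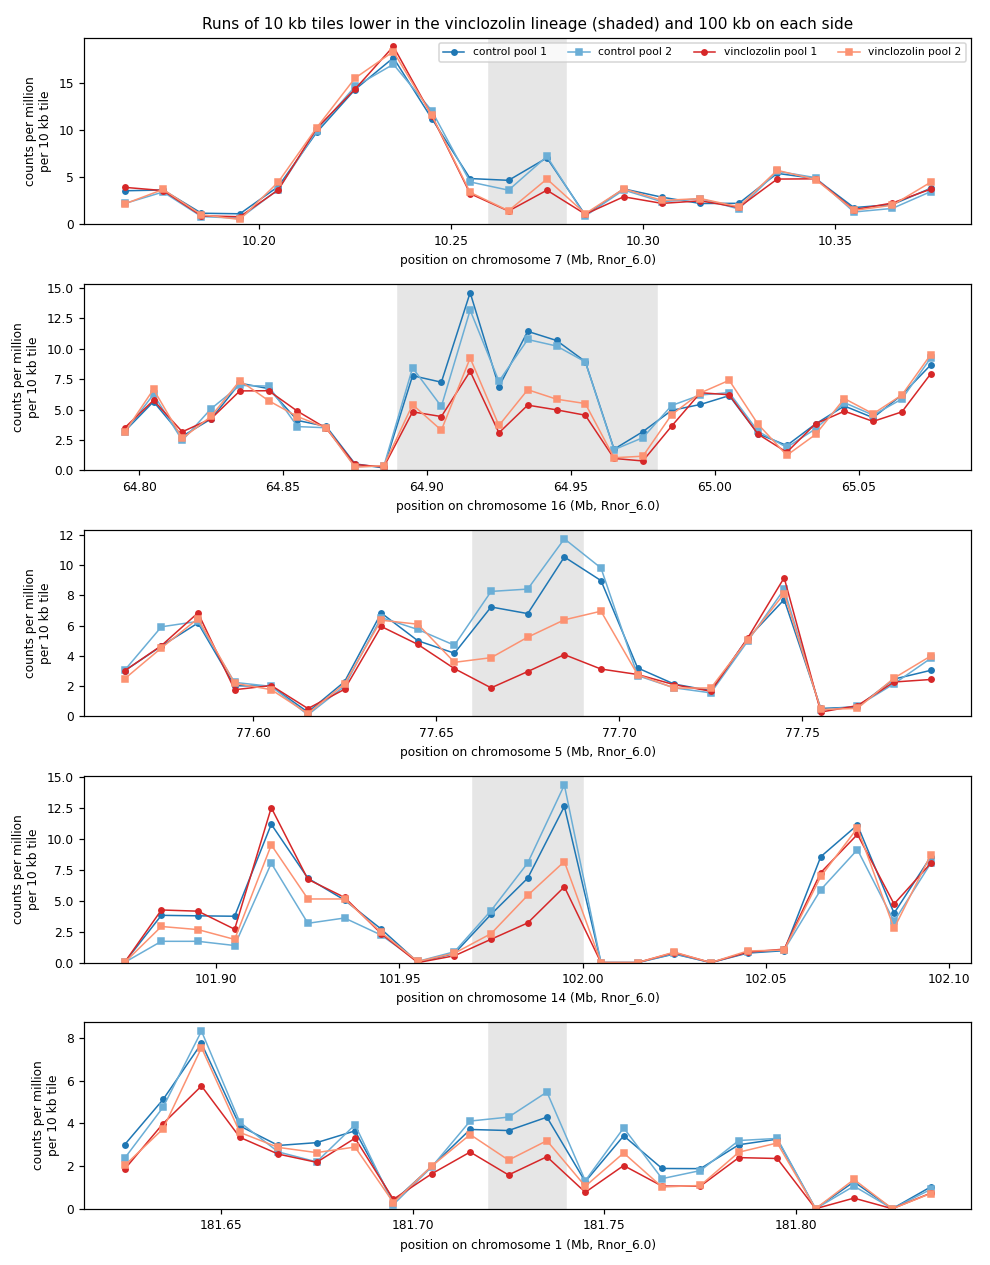
CPM (scaled to total window counts) per 10 kb tile over the 5 runs (shaded) and 100 kb on each side, against position in Mb; 1 line per pool, control pools blue and vinclozolin pools red. Inside the shaded runs both red lines lie below both blue lines, and at 0.462 to 0.560 of the control mean over each run.

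By chromosome, windows at an unadjusted p under 0.001 were 228 higher and 347 lower in the vinclozolin lineage, where chance would give 2318 in all. Lower windows numbered 34 on chromosome 16 against 11.6 from its share of tested windows, and 21 of the 34 lay in the 90 kb run. On chromosome 14 there were 33 against 14.5, of which 16 lay in the run there. The X chromosome held 25 lower windows against 10.5 and 2 higher windows against 6.92, with a median log2 fold change of −0.09. Without control pool 2, whose X signal stood above the other pools, lower windows numbered 5 against 5.82 on X, 19 against 6.73 on chromosome 16 and 8 against 8.42 on chromosome 14.

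The mean count per window on X relative to the autosomes was 0.514 in control pool 1, 0.570 in control pool 2, 0.497 in vinclozolin pool 1 and 0.495 in vinclozolin pool 2. The lineage means were 0.542 ± 0.040 and 0.496 ± 0.001 (SD, n = 2 each), a difference of −0.046, or −0.018 without control pool 2. A two-sided exact permutation test gave p = 0.33, the smallest value that 2 against 2 pools allow. On Y the values were 0.973, 0.876, 0.888 and 1.03 in the same order, and the lineage means of 0.924 ± 0.069 and 0.958 ± 0.10 (SD, n = 2 each) differed by less than the spread between pools (exact permutation p = 0.667).

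**Figure D3:**
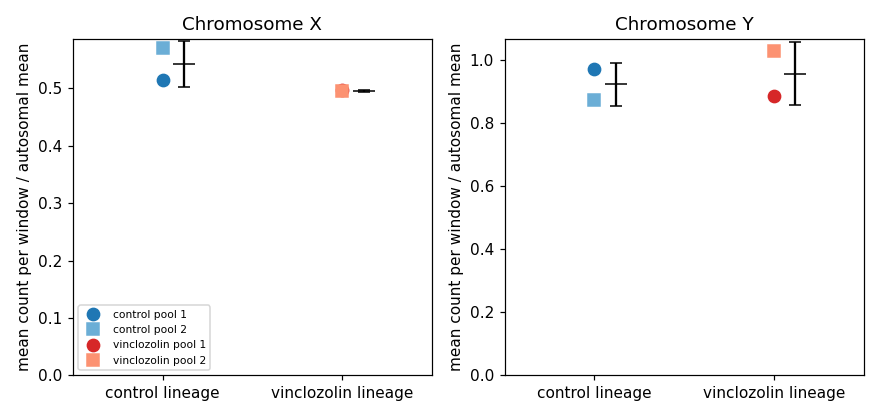
Mean count per 100 bp window on chromosomes X and Y divided by the autosomal mean, 1 point per pool (circles pool 1, squares pool 2), with the lineage mean and SD as a black bar beside the points (n = 2 each). On X, control pool 2 sits at 0.570 and the other 3 pools between 0.495 and 0.514; on Y the lineages overlap.

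Enrichment differed between the lineages by less than the spread between pools. The 1% of windows with the highest counts took 12.8% ± 1.6 of all counts in the control and 13.2% ± 0.9 in the vinclozolin lineage (SD, n = 2 each; exact permutation p = 1). Mitochondrial windows took 0.024% ± 0.004 and 0.025% ± 0.009 (exact permutation p = 1). On average, pools of a lineage were no closer to each other than to the other lineage. Across the tested windows, which are not independent replicates, Pearson's r of log2 CPM was 0.711 between the control pools and 0.600 between the vinclozolin pools, and between lineages it ranged from 0.640 (control pool 2 with vinclozolin pool 1) to 0.767 (control pool 2 with vinclozolin pool 2). Spearman's rho was 0.597 and 0.492 within lineages and 0.536 to 0.672 between them. The mean r was 0.656 within and 0.692 between lineages.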

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

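Alternatives for the 10 kb tiles, the X and Y ratios in windows with a mean count under 5, the trend corrections, the earlier quasi-likelihood method and the tiles of 100 kb and 1 Mb were chosen after seeing the data; the others were planned. The 24 named regions passed an adjusted p of 0.05 in 41 of 341 combinations of region and alternative. Of the 41, 17 came from the replicate block by pool number with the trend correction and 7 from the block alone. Fits without 1 pool, the exact test and the filter at a mean count of 5 gave the rest. The direction of the 24 regions did not reverse, but the naming rule, which asked for separated pools, nearly fixes that, so it says nothing about stability. With other sets of windows, the lineage differences in X, Y and the top 1% share and the agreement of pools kept their sign. Leaving out 1 of 2 pools cannot shift a lineage mean by its own SD, so that says nothing about stability. Without some single pools the differences in Y, the top 1% share and the mitochondrial share changed sign, and that in X fell from −0.046 to −0.018 without control pool 2. At this depth, 0 of 67 simulated 2-fold changes of a window were called. Except where fewer windows or pools entered the fit, the cause of the moves below was not tested. The correction for CpG density, with and without the block, and the promoter, gene list and CpG feature results were not run.

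Without 1 pool at a time, the lone pool of a lineage is assumed to vary like the other lineage, and lineage is partly mixed with pool number. The number of windows past an adjusted p of 0.05 (0 with all pools) then ranged from 0 (without control pool 1) to 1215 (without vinclozolin pool 2), windows at p under 1e-04 from 0 to 1747 higher and from 1 to 673 lower, merged regions from 0 to 1128 higher and from 1 to 284 lower, 10 kb tiles past an adjusted p of 0.05 from 3 to 41, and runs of tiles from 2 to 10 lower and from 1 to 18 higher.

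The pool numbers are shared between lineages, but no label says that they mark a batch, and the differences between pools 1 and 2 correlated at 0.18 across windows between lineages. With the number as a replicate block, 10 windows passed an adjusted p of 0.05 (4 higher, 6 lower), 118 higher and 147 lower windows lay at p under 1e-04, and 111 higher and 113 lower regions were formed. For tiles of 10 kb the block gave 46 tiles past the threshold, with 15 lower and 4 higher runs, and the best tile of each of the 5 runs had an adjusted p of 3.69e-06 or less, as did the X tile from 150610001 (2.97e-22, or 1.14e-24 with the trend correction). With the block and the mean count trend correction together there were 79 windows past the threshold, 397 higher and 208 lower windows at p under 1e-04, 382 higher and 121 lower regions, 52 tiles, and 15 lower and 9 higher runs.

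The trend correction alone gave 36 higher and 61 lower windows, 34 higher and 39 lower regions and 6 tiles. Scaling by total counts gave 8 higher and 13 lower windows, 6 higher and 11 lower regions and 3 tiles. The exact test passed 4 windows at an adjusted p of 0.05: those from 71473301 and 71473401 on chromosome 13 and from 73275901 on chromosome 7, which were higher, and from 77669201 on chromosome 5, which was lower. A mean count of at least 5 passed 3 windows (the same windows on chromosomes 13 and 7), with 91 higher and 122 lower windows at p under 1e-04 and 87 higher and 104 lower regions. A mean count of at least 20 gave 4 higher and 13 lower windows and 4 higher and 10 lower regions. The earlier quasi-likelihood method gave 9 higher and 24 lower windows and 8 higher and 19 lower regions. Using 1 window in every 5 gave 2 higher and 9 lower, 1000 bp tiles 11 higher and 21 lower, 100 kb tiles 0 higher and 2 lower, and 1 Mb tiles 0 higher and 0 lower. DESeq2's Wald test and the fit with no filter beyond 1 read each gave 0 higher and 0 lower windows at p under 1e-04. A threshold of p 1e-05 gave 3 higher and 7 lower regions, and 1e-03 gave 218 higher and 295 lower.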

Other observations

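The tests of explanations below were all chosen after the patterns had been seen, and so were the counts of tiles by pool.

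Tiles of 1000 bp that held at least 15 reads in 1 pool and 0 in the other 3 numbered 155 in control pool 1, 5 in control pool 2, 10 in vinclozolin pool 1 and 10 in vinclozolin pool 2. The reverse, no read in 1 pool and at least 15 in each of the other 3, occurred at 6 tiles in control pool 1, 141 in control pool 2, 261 in vinclozolin pool 1 and 220 in vinclozolin pool 2. Adjacent tiles on chromosome 6 from 123449001 to 123451000 had summed window counts of 55 and 53 in vinclozolin pool 2 alone. A tile on chromosome 2 from 183636001 to 183637000 had 54 in the same pool, and tiles on the X chromosome from 79465001 to 79467000 had 35 and 36 in control pool 1 alone.

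The 5 runs of 10 kb tiles with lower signal in the vinclozolin lineage stood at 0.462 to 0.560 of the control level. On chromosomes 7, 16, 5 and 1, the lower signal was not confined to windows with a mean count of 5 or more. Low-count windows at least 300 bp from these were lower in both vinclozolin pools than in both control pools. They held 2.77% to 10.9% of the window counts the runs were chosen on. The smallest log2 difference was −1.09, which 0.277% of 211563 single 10 kb tiles genome-wide reached with separated pools. That share cannot show the drop to be unusual, because the runs were chosen as low and are longer than 1 tile. The low-count windows cannot decide on a methylation change confined to enriched windows. Low-count windows also hold precipitated DNA, and 300 bp is only the programmed fragment length. A copy number or haplotype difference between the pooled animals is a candidate explanation there. The median difference was −1.16 in the low-count windows and −1.01 in those with a mean count of 10 or more, but single runs differed. Low-count windows fell more than those of 10 or more on chromosomes 16 (−1.09 against −0.745) and 5 (−1.48 against −1.15). The values were closer on chromosomes 7 (−1.09 against −1.03) and 1 (−1.22 against −1). A methylation difference, over the whole stretch or in enriched windows only, and a lineage difference by ancestry stay open, untested. On chromosome 14 the low-count windows held 4 reads, too few to compare. The 3 splits of the 4 pools are too few to judge chance: 2 of them gave at least 5 runs, with 5 for the lineages and 1123 for the highest other split.

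The pool numbers separated the pools at far more windows than lineage did. Splitting the pools by number gave 3425 windows past an adjusted p of 0.05 and 19609 tiles of 10 kb, against 0 windows and 1 tile for the lineages, which points to a structure of the pools other than lineage. The third split, control pool 1 and vinclozolin pool 2 against control pool 2 and vinclozolin pool 1, gave 2 windows and 0 tiles. At p under 1e-04 it gave 33 windows, against 58 for the lineages. A trend of enrichment with mean count is argued against as the whole cause, since 7287 windows passed in the split by number after its removal. So is sequencing depth, since pool 1 had 1.18 times the reads of pool 2 in the control but 0.654 times in the vinclozolin lineage. The share of counts in tested windows followed the number. It was 40.3% and 40.4% in control and vinclozolin pools 1, and 46.6% and 47.3% in control and vinclozolin pools 2. Whether the efficiency of precipitation differed by number was not tested. Shared handling of same-numbered pools may be the cause, but no label names a day or batch and it was not tested. With 3 splits chance cannot be judged: 2 of them gave at least as many windows at p under 1e-04 as the lineages, with 58 for the lineages and 4026 for the highest other split.

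Control pool 2 had 1.14 times the X signal of the mean of the other pools. A few loci on X are argued against, because control pool 2 was highest in 97.5% of the 160 bins of 1 Mb. An enrichment difference shared by the pools numbered 2 would put vinclozolin pool 2 above both pools numbered 1 on X. It lay below control pool 1 over all windows (0.495 against 0.514). It was also below control pool 1 in windows with a mean count under 5 (0.5217 against 0.5225) and of 10 or more (0.944 against 0.966). Against vinclozolin pool 1 it was lower over all windows (0.495 against 0.497). In the same 2 classes it was higher than vinclozolin pool 1 (0.522 against 0.508 and 0.944 against 0.920), so this explanation is not settled. Cells of female embryos in the pool are a candidate explanation that cannot be told apart from pool spread: a female share of 13.6% would give the X excess and a Y ratio of 0.864, the measured ratio was 0.909, and the Y values of the other 3 pools had an SD of 0.074 relative to their mean. The excess was 1.23 and 1.09 in these 2 classes, so the implied share depends on the windows used, and no explanation by lineage was tested.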
